A study of Mus musculus with 45 samples.

How the data were processed

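The study profiled 45 samples of mouse trophoblast with Agilent one-colour arrays, 1 sample per array. The 14 groups were colony types 1, 2 and 4 of the lines B6TS4, EGFP-TS3.5 and XGFP, the line CD1-TS in defined medium, and extraembryonic ectoderm (ExE) and ectoplacental cone (EPC) of the B6 and ICR strains. Per the labels, the conventional lines grew on mitomycin-treated embryonic fibroblasts in medium with 20% serum, 25 ng/ml FGF4 and heparin. RNA came from 30 to 50 colonies per sample and was amplified in 2 rounds, and 5 µg of amplified RNA was labelled with Cy3. Groups were taken from the labels.

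Each array has a scanner file. Per the file headers, the intensity values were extracted with Agilent Feature Extraction 10.5.1.1 (protocol GE1_105_Dec08, array design 028005, grid annotated on mm9), and the processed signal was background-subtracted and detrended within the array but not scaled between arrays. Per the file headers, the median spot signal and median local background are intensities too, and the other columns used are flags of 0 or 1 for spots well above background, non-uniform or outlying. Each array had 62976 spots, 59305 of them not controls, which held 55681 probes. The deposited value table holds log2 values that the authors scaled and centred in a way they did not state. In it every probe had a median of 0 over the arrays, and 44 columns followed log2 of the processed signal minus the array's 75th percentile, minus the probe's median (correlation of at least 0.9981). The column medians ran from -0.45 to 0.64, so the centring leaves levels unknown while differences between samples stay readable. The column of EGFP-TS3.5 type 1 replicate 2 did not follow its scanner file (correlation 0.1815). The comparisons used the scanner files, this array included, and its column and its omission were alternatives.

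Depth on an array is signal over background. The 75th percentile of the processed signal was 292.3 to 1697.5, 39.04% to 72.36% of probes were well above background, and no spot was saturated. The files place the arrays on 6 slides scanned on 2 days. Spots marked as non-uniform or population outliers (115 to 402 per array) were left out, spots of 1 probe were averaged on the log2 scale, and the array's 75th percentile over non-control probes was subtracted. Probes were kept when well above background on every array of at least 1 group, which left 37881 of 55681. Probes were given current mouse gene symbols through the sequence accession the files name for them, with no coordinates, which gave 27235 probes 1 symbol each and 28446 probes none. A gene was represented by its probe with the highest mean, and 16423 genes were tested, 3985 of them with several kept probes.

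All 45 arrays entered 1 limma fit (lmFit and eBayes, limma 3.58.1, R 4.3.3) with a mean for each group, 31 residual degrees of freedom and 2.28 prior degrees of freedom. The 6 comparisons were types 4 and 1, types 2 and 1, and types 4 and 2, each averaged over lines, EPC and ExE averaged over strains, the defined line and type 1 colonies of EGFP-TS3.5 and XGFP, and type 1 colonies and ExE of the same strain. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change. Whether the difference between types 4 and 1 varied by line, and that between EPC and ExE by strain, was tested by limma at an adjusted p under 0.05 with no fold minimum. Where a gene was not well above background on any array of its lower side, its change is given as a lower bound, from the lowest signal well above background on those arrays. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

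Gene lists were tested by camera on the moderated statistics with a preset correlation of 0.01, with adjustment over 156 tests, 26 lists in 6 comparisons. The lists held 632 members, 620 of them on the array. They were trophoblast stem cell, ectoplacental cone and spongiotrophoblast, trophoblast giant cell, syncytiotrophoblast, FGF and ERK targets, activin, nodal and BMP, Wnt targets, actin, SRF and YAP targets, epithelial junction and keratin, mesenchymal transition, fibroblast, mitosis and DNA replication, and CDK inhibitor and p53 targets. The others were cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, unfolded protein and amino acid stress, immediate early, interferon response, imprinted, pluripotency and epiblast, extraembryonic endoderm, maternal decidua, leukocyte and blood, endothelial, and X and Y linked. With the correlation estimated from the residuals, 11 of the 53 called tests were still called, and the report gives that p beside each call. The cone score, from genes chosen on the tissue arrays, was compared by exact permutation of type labels within lines, two-sided.

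Genes were named by a rule. It took the 10 largest rises and 10 largest falls of each comparison among called genes with the same sign in every line or strain, measured on every array of a group of the higher side, passing over clone and predicted names. It always took Cdx2, Eomes, Elf5, Esrrb, Tfap2c, Sox2, Fgfr2, Ascl2, Hand1, Prl3d1, Gcm1, Syna, Cdh1 and Col1a1. Tpbpa and Prl2c2 were on that list but not among the tested genes. It added up to 4 called members of each list, any member that moved against the rest, and the 5 smallest p of each interaction. The values, tests, thresholds, lists, rule and most alternatives were fixed before the data were examined. Alternatives covered the scaling, background correction, source of values, probe filter, floor, outlier spots, gene summary, variance model, arrays in the fit, threshold, replicate number, slide, each line or strain alone and each array left out in turn. Those on the median signal, signal level, slide as a random block, slide with fewer lines, and doubtful arrays were chosen after the data were seen. The steps were tested on simulated data, with 50 genes changed by each of several sizes. In the 6 comparisons a log2 change of 1 was called for 16% to 40% of genes and of 3 for 78% to 96%. At most 8 unchanged genes were called in each. All 26 shifted and none of 26 unshifted lists were called, which does not test correlation in the real lists.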

Results

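Gene expression was measured on 45 one-colour arrays of mouse trophoblast, with 1 sample per array and 14 groups of 2 to 4 arrays. Trophoblast stem cells are the self-renewing precursors of the placental trophoblast. Cultured colonies of 3 numbered types came from 3 conventional lines grown with serum and FGF4 on feeder fibroblasts. B6TS4 gave 4 arrays of type 1, 2 of type 2 and 3 of type 4. EGFP-TS3.5 gave 3 of type 1, 3 of type 2 and 4 of type 4, and XGFP gave 3 of type 1, 4 of type 2 and 4 of type 4. CD1-TS, a line grown in chemically defined medium, gave 3 arrays. Extraembryonic ectoderm (ExE) holds the stem cells in the embryo, and trophoblast differentiates in the ectoplacental cone (EPC). Both tissues were taken at embryonic day 6.5 from the B6 and ICR strains, with 3 arrays of each tissue and strain. The 75th percentile of the signal lay between 292.3 and 1697.5 per array. Every array of B6 origin was on slides 1 and 2, scanned on 1 day, where 57.15% to 72.36% of probes were well above background. All other arrays were on 4 slides of another day, with 39.04% to 61.15%. Values given with a gene are log2 fold changes ± SE unless a fold is named, and the number of arrays limits their precision. Array counts beside a gene give those on which it was well above background, where this was not every array. On 1 array, EGFP-TS3.5 type 1 replicate 2, the scanner values did not follow the column of the deposited value table with its label (correlation across probes 0.1815, and at least 0.9981 on the other 44 arrays). Without it 919 genes were called between types 4 and 1 and 48 between types 2 and 1. The labels do not say whether arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples.

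Type 4 colonies were set against type 1 colonies of the same line to ask what separates these colony types (11 and 10 arrays, averaged over 3 lines). Several placental genes were higher in type 4. Plac1, a gene of placental growth, rose by 3.62 ± 0.83 (8 of 10 type 1 arrays, adjusted p = 0.00426). Ascl2, a transcription factor of the ectoplacental cone lineage, rose by 3.01 ± 0.64 (adjusted p = 0.00219) and Pparg, a nuclear receptor of labyrinth trophoblast, by 2.70 ± 0.73. Prl3d1 and Prl3d2, placental lactogens of trophoblast giant cells, rose by 2.78 ± 0.84 and 3.74 ± 0.97. They were well above background on 9 of 11 type 4 and 6 of 10 type 1 arrays and on 7 of 11 type 4 and 2 of 10 type 1 arrays. XGFP had the largest of the 3 differences for each of these 5 genes, with 9.91 for Plac1, 7.32 for Ascl2 and 6.85 for Pparg. The lines differed in the size of the Plac1 and Ascl2 changes (line by type interaction, adjusted p = 0.00176 and 0.00409). Other large rises were Bst1, a cell surface ADP-ribosyl cyclase (3.90 ± 0.80, measured on 10 of 11 type 4 and 5 of 10 type 1 arrays), Myl4, a myosin light chain (3.51 ± 0.50, 7 of 10 type 1 arrays), and Ednra, an endothelin receptor (3.35 ± 0.59, 7 of 11 type 4 and 4 of 10 type 1 arrays). Utrn, which links actin to the membrane (3.23 ± 1.07, 6 of 10 type 1 arrays), and Serpinb9f, a protease inhibitor (3.10 ± 1.02, 7 of 10 type 1 arrays), were next.

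Among the largest falls in type 4 was Cwh43, a gene of glycolipid anchor remodelling (-4.25 ± 0.70, adjusted p = 0.000231, 7 of 11 type 4 arrays). Others were Prom2, a protein of epithelial membrane protrusions (-3.69 ± 0.61, adjusted p = 0.000229, 6 of 11 type 4 arrays), and Galnt3, an enzyme of protein glycosylation (-2.87 ± 0.48, 10 of 11 type 4 arrays). Prom2 was 0.30 higher with slide as a block in B6TS4 and XGFP. Cdh1, the epithelial adhesion molecule E-cadherin, fell (-1.39 ± 0.20, adjusted p = 7.24e-05), as did Epcam (-1.06 ± 0.19) and Grhl2, a regulator of epithelial genes (-1.28 ± 0.24, although 0.10 in XGFP). The keratin Krt19 rose (1.59 ± 0.29, although -0.39 in B6TS4). Of 30 measured genes of epithelial junctions and keratins, 1 rose and 3 fell, also when adjusted over the list alone. Epithelial genes ranked lower as a list (median -0.14, camera adjusted p = 9.61e-05, but adjusted p = 0.0927 with an estimated correlation). Other large falls were Ephb1, an ephrin receptor (-3.21 ± 0.93, 4 of 11 type 4 and 9 of 10 type 1 arrays), Ltbp2, which binds the extracellular matrix (-3.07 ± 0.63, 9 of 11 type 4 arrays), Adrb1, an adrenergic receptor (-2.91 ± 0.56, 7 of 11 type 4 arrays), and Pde8b, a cAMP phosphodiesterase (-2.91 ± 0.79, 7 of 11 type 4 arrays). Shisa2, an inhibitor of FGF and Wnt receptors (-2.90 ± 0.63, 8 of 11 type 4 arrays), She, a signalling adaptor (-3.09 ± 1.02, 8 of 11 type 4 arrays), and Nars2, a mitochondrial tRNA synthetase (-3.01 ± 0.79, 4 of 11 type 4 arrays), fell by about as much.

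The transcription factors that hold the stem cell state were measured on every array of both types and did not pass the test together with the 2-fold minimum. Cdx2 differed by -0.25 ± 0.30, Esrrb by -0.10 ± 0.28 (-1.04 in XGFP and 0.62 in B6TS4), Tfap2c by 0.05 ± 0.19 and the FGF receptor Fgfr2 by -0.10 ± 0.20. Smaller than 2-fold were the differences of Eomes, -0.74 ± 0.20 (adjusted p = 0.0112, but -1.63 in XGFP, called there), Elf5, -0.72 ± 0.13 (adjusted p = 0.00041), and Sox2, -0.68 ± 0.17 (adjusted p = 0.0063). Of 23 measured stem cell genes, Rhox6 (1.28 ± 0.29) and Rhox9 (1.12 ± 0.32) rose and Zic3 (-2.14 ± 0.37, 8 of 11 type 4 arrays) and Sox21 (-1.39 ± 0.26) fell, with the same counts adjusted over the list alone. The list ranked lower (median -0.25, camera adjusted p = 7.77e-05, and adjusted p = 0.0193 with an estimated correlation). The differences of the 2 Rhox genes and Zic3 were largest in XGFP, at 3.81, 3.22 and -6.27, and had the opposite sign in EGFP-TS3.5, at -0.34, -0.02 and 0.18. Of 21 targets of FGF and ERK signalling, 4 fell (4 adjusted over the list alone) and none rose. They were the immediate early factor Egr1 (-1.80 ± 0.57), the cyclin Ccnd1 (-1.57 ± 0.27, although 0.16 in EGFP-TS3.5), Phlda1 (-1.03 ± 0.26) and the ERK phosphatase Dusp6 (-1.02 ± 0.30, although 0.34 in B6TS4). The list ranked lower (median -0.48, camera adjusted p = 2.53e-05, but adjusted p = 0.111 with an estimated correlation).

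Lists of differentiated trophoblast were not called as wholes. Of 19 giant cell genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.90, camera adjusted p = 0.212). Hand1, a giant cell factor, differed by 0.34 ± 0.15, and Mmp9, a matrix protease, fell (-1.50 ± 0.31, although 0.32 in EGFP-TS3.5). Of 20 genes of the ectoplacental cone and spongiotrophoblast, 3 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.954). Among the rises the kinase gene Nrk was at least 1.46-fold higher and not well above background on any type 1 array. Of 18 genes of syncytiotrophoblast, the transcription factor Tfeb (1.14 ± 0.20) and the transporter Slc16a1 (1.02 ± 0.25, 10 of 11 type 4 and 9 of 10 type 1 arrays) rose and none fell (the same adjusted over the list alone, camera adjusted p = 0.209). The master regulator Gcm1 differed by 0.75 ± 0.24 and the syncytin gene Syna by 0.48 ± 0.71 (5 of 11 type 4 and 5 of 10 type 1 arrays). Glycolysis and hypoxia genes ranked higher (median 0.52, camera adjusted p = 7.77e-05, but adjusted p = 0.188 with an estimated correlation). Of 26 members 23 were above 0 and 3 rose (3 adjusted over the list alone), the glucose transporter Slc2a3 (1.66 ± 0.29), the glycolytic enzyme Aldoc (1.22 ± 0.23) and P4ha2 (1.07 ± 0.18, -0.27 in B6TS4).

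Of 18 genes of mesenchymal transition, 3 rose and none fell (the same adjusted over the list alone), the matrix gene Tgfbi (2.29 ± 0.46, 8 of 10 type 1 arrays) and the transcription factors Snai1 (1.22 ± 0.31) and Zeb1 (1.19 ± 0.31). The list was not called (camera adjusted p = 0.954). Zeb1 was 1.89 in B6TS4, 2.45 in EGFP-TS3.5 and -0.76 in XGFP. Of 29 fibroblast genes, which feeder cells would carry, Crabp1 (-1.56 ± 0.39) alone was called (1 adjusted over the list alone). The list ranked lower (median -0.31, camera adjusted p = 0.0088, but adjusted p = 0.31 with an estimated correlation). The collagen gene Col1a1 differed by 0.02 ± 0.71 (10 of 11 type 4 arrays). Mitosis and DNA replication ranked higher (median 0.22, adjusted p = 0.0464, and adjusted p = 0.366 with an estimated correlation). CDK inhibitors and p53 targets ranked lower (median -0.14, adjusted p = 0.0125, and adjusted p = 0.249 with an estimated correlation). So did cholesterol synthesis (median -0.09, adjusted p = 0.00908, and adjusted p = 0.366 with an estimated correlation). No member of these 3 lists was called, also adjusted over the list alone. Of 27 interferon response genes, Ifi27 fell (-2.37 ± 0.51, 10 of 11 type 4 arrays) and none rose (the same adjusted over the list alone). Interferon genes ranked lower as a list (median -0.10, adjusted p = 0.031, and adjusted p = 0.297 with an estimated correlation).

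In total, 744 of 16423 genes were called between types 4 and 1 by limma, 481 higher and 263 lower in type 4. Of these, 395 and 194 had the same sign in all 3 lines. The difference was called for 798 genes in B6TS4, 204 in EGFP-TS3.5 and 2733 in XGFP. Between lines, 2677 genes differed in it (line by type interaction, 4590 without B6TS4 type 4 replicate 2). B6TS4 and EGFP-TS3.5 shared 25 falls where 2.28 were expected by chance, and 8 rises where 2.64 were expected. The correlation of fold changes across genes, which are not independent replicates, was 0.175 between B6TS4 and EGFP-TS3.5, 0.0458 between B6TS4 and XGFP and 0.00567 between EGFP-TS3.5 and XGFP. The balance of rises and falls rested on the scaling. The median of all genes was 0.19, and quantile scaling, with a median of 0.01, gave 227 rises and 365 falls. With slide as a block in B6TS4 and XGFP 297 genes were called, against 1331 without it. Within slide 1 the B6TS4 types differed in 889 genes, but from 1 type 4 array, the dimmest of all, set against 4 with the spread of all groups. In EGFP-TS3.5 no type 4 array shared a slide with another type, so type and slide cannot be told apart there. In XGFP types 4 and 1 shared none, and 1 type 2 array links their slides. Leaving out B6TS4 type 4 replicate 3 gave 494 genes.

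**Figure D1:**
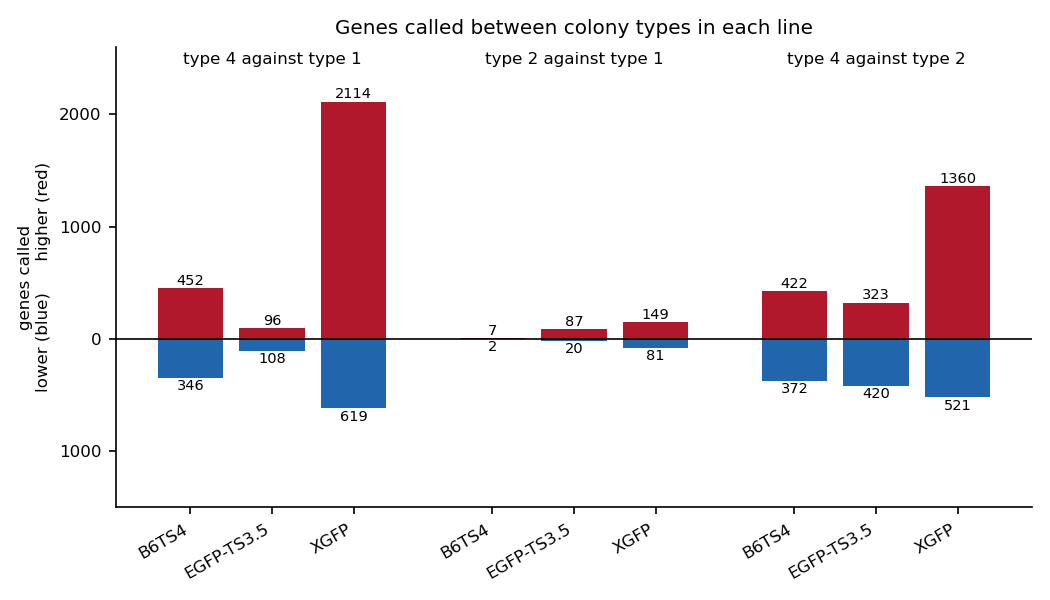
Bars give the number of genes called higher (red, upwards) and lower (blue, downwards) for each pair of colony types in B6TS4, EGFP-TS3.5 and XGFP. Between types 4 and 1, XGFP had 2114 rises and 619 falls, B6TS4 452 and 346, and EGFP-TS3.5 96 and 108.

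**Figure D2:**
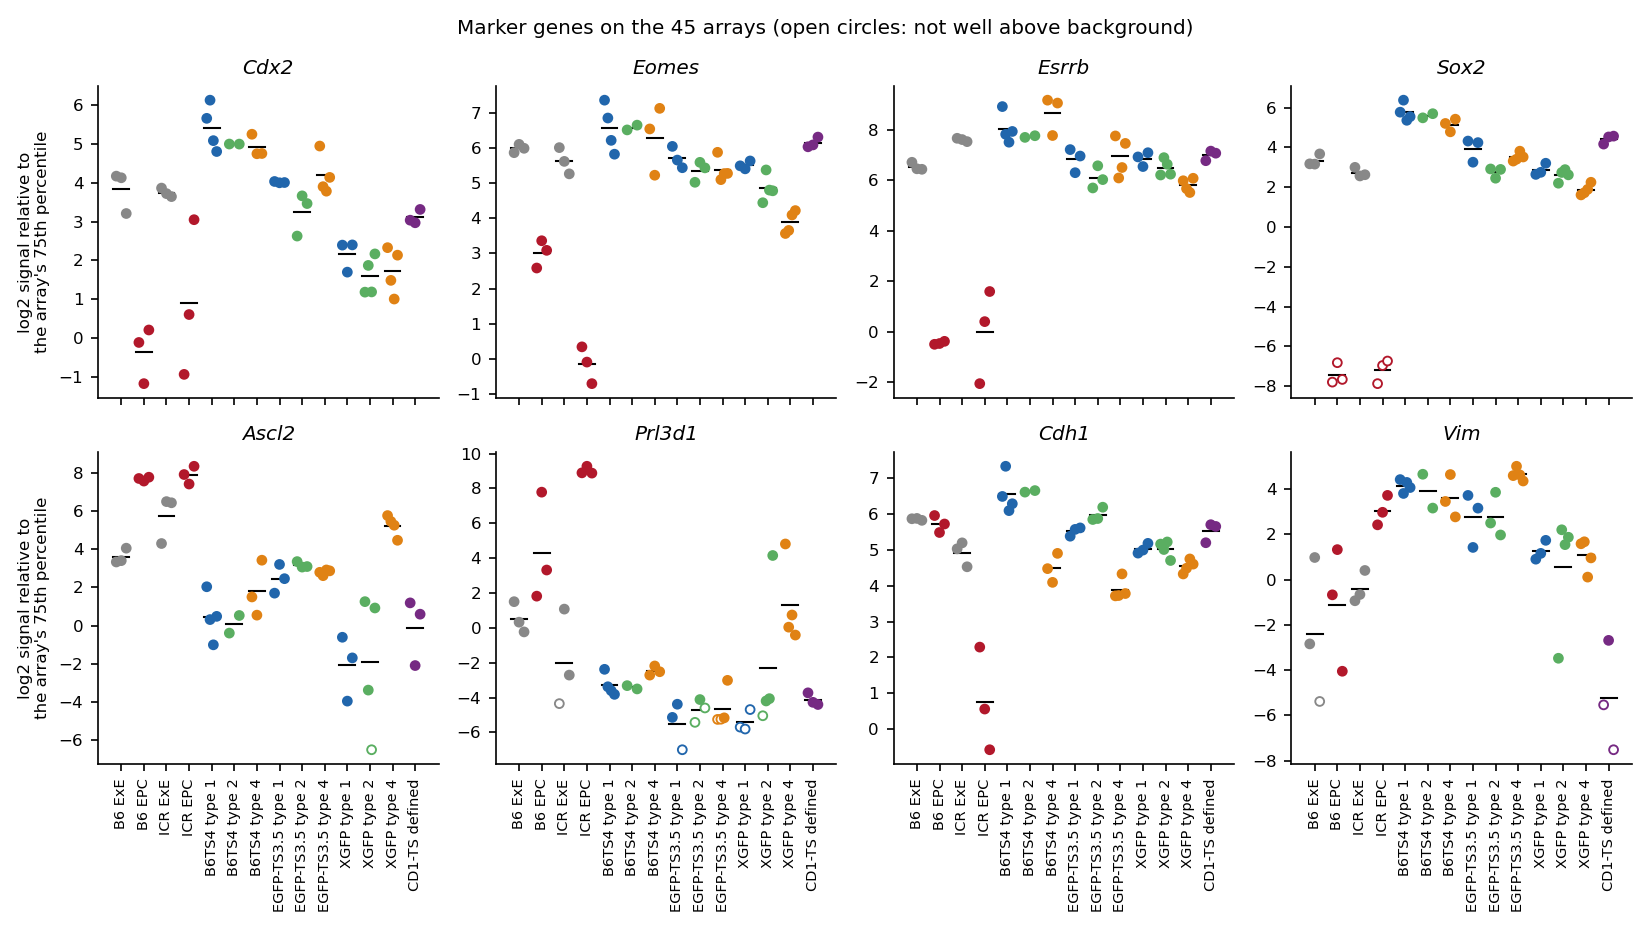
Each panel plots 1 gene, each point an array and each bar a group mean, as log2 signal relative to the array's 75th percentile, with open circles where the probe was not well above background. Cdx2, Eomes and Esrrb are lower in the cone than in the ectoderm, and Ascl2 and Prl3d1 are higher in XGFP type 4 than in XGFP type 1.

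Type 2 colonies were compared with type 1 colonies to place type 2 (9 and 10 arrays). Vnn1, which releases pantothenate, rose by 4.72 ± 0.86 (adjusted p = 0.0095, 7 of 10 type 1 arrays), Plac1 by 4.07 ± 0.89 (8 of 10 type 1 arrays, adjusted p = 0.0355). Myl4 rose by 3.98 ± 0.53 (7 of 10 type 1 arrays, adjusted p = 0.00023, although 0.11 in B6TS4) and Cers3, a ceramide synthase, by 3.55 ± 0.73 (7 of 9 type 2 and 4 of 10 type 1 arrays). The interferon-induced antiviral gene Rsad2 (3.06 ± 0.65, 6 of 9 type 2 and 5 of 10 type 1 arrays), the nuclear receptor corepressor Nrip1 (2.64 ± 0.53, 8 of 9 type 2 and 6 of 10 type 1 arrays), and the thiamine transporter Slc19a3 (2.48 ± 0.54, 7 of 10 type 1 arrays) rose. So did the small heat shock protein Cryab (2.00 ± 0.33), Oga, which removes O-GlcNAc from proteins (1.83 ± 0.41, 8 of 9 type 2 and 6 of 10 type 1 arrays), and the epithelial surface protein Tacstd2 (1.61 ± 0.37). Rhox6 (1.48 ± 0.31) and Rhox9 (1.46 ± 0.34), homeobox genes of the stem cell list, rose too. Among 6 falls were Tnfsfm13 (-2.34 ± 0.53, 6 of 9 type 2 arrays) and Pgbd5 (-2.10 ± 0.49, 8 of 9 type 2 arrays), and Spink2 was at least 1.28-fold lower, not well above background on any type 2 array. Lrrc3, Rap2c and Lrrc10b, also called lower, were not well above background on any type 2 array and on at most 6 of 10 type 1 arrays. The glucose transporter Slc2a3 (1.57 ± 0.31, -0.22 in B6TS4) and Dppa5a, a gene of pluripotent cells (2.32 ± 0.39, 8 of 10 type 1 arrays, -0.14 in B6TS4), rose. Cdx2 (-0.58 ± 0.32), Eomes (-0.34 ± 0.21), Elf5 (-0.20 ± 0.13), Esrrb (-0.47 ± 0.30), Sox2 (-0.54 ± 0.18), Hand1 (-0.23 ± 0.16) and Cdh1 (0.17 ± 0.22) did not pass the test. Neither did Tfap2c (-0.47 ± 0.20), Fgfr2 (0.17 ± 0.21), Ascl2 (0.16 ± 0.68, 8 of 9 type 2 arrays), Prl3d1 (1.26 ± 0.90, 6 of 9 type 2 and 6 of 10 type 1 arrays), Gcm1 (0.18 ± 0.26), Syna (-0.02 ± 0.76, 4 of 9 type 2 and 5 of 10 type 1 arrays) and Col1a1 (-0.15 ± 0.76, 6 of 9 type 2 arrays).

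Genes of epithelial junctions and keratins ranked higher in type 2 (28 of 30 above 0, median 0.31, camera adjusted p = 7.85e-07, and adjusted p = 0.0215 with an estimated correlation). None was called over all genes, and 3 were higher adjusted over the list alone. Interferon response genes also ranked higher, with 1 of 27 called and 3 adjusted over the list alone (median 0.37, camera adjusted p = 0.000391, but adjusted p = 0.102 with an estimated correlation). Targets of FGF and ERK ranked lower with no called member of 21 (none adjusted over the list alone, median -0.37, camera adjusted p = 0.000132, but adjusted p = 0.161 with an estimated correlation). Actin, SRF and YAP targets ranked higher (median 0.35, adjusted p = 0.0407, but adjusted p = 0.506 with an estimated correlation). Endothelial genes ranked lower (median -0.43, adjusted p = 0.0168, but adjusted p = 0.183 with an estimated correlation). Neither list had a called member, also adjusted over the list alone.

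In total, 35 genes were called between types 2 and 1, 29 higher and 6 lower, and 1378 of 16423 had an unadjusted p under 0.05. By line, 9 genes were called in B6TS4, 107 in EGFP-TS3.5 and 230 in XGFP. With slide as a block 20 were called, and within single slides 10 in B6TS4, 106 in EGFP-TS3.5 and 52 in XGFP (from 1 type 2 array). Leaving out single arrays moved the count by over 1.5 times. It was 21 and 16 without B6TS4 type 1 replicates 3 and 4, 3 and 20 without B6TS4 type 2 replicates 1 and 2. It was 17 and 22 without EGFP-TS3.5 type 2 replicates 1 and 3, 19 without XGFP type 1 replicate 3 and 18 without XGFP type 2 replicate 4.

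Type 4 colonies were also compared with type 2 colonies (11 and 9 arrays), and epithelial genes were among the falls. Tmprss2, a membrane serine protease of epithelia, fell by 4.43 ± 0.46 (adjusted p = 4.43e-07, 6 of 11 type 4 arrays). Ocln, the tight junction protein occludin, fell by 3.81 ± 0.68 (adjusted p = 0.000597, 4 of 11 type 4 and 8 of 9 type 2 arrays). Mal and Mal2, carriers of apical membrane traffic, fell by 4.59 ± 0.88 (7 of 11 type 4 arrays) and 3.80 ± 0.68 (10 of 11 type 4 arrays). Prom2 (-4.25 ± 0.63, 6 of 11 type 4 and 7 of 9 type 2 arrays), Cwh43 (-4.03 ± 0.73, 7 of 11 type 4 arrays), and Galnt3 (-3.61 ± 0.51, 10 of 11 type 4 arrays) fell as well. So did the claudin Cldn7 (-2.02 ± 0.36), Cdh1 (-1.57 ± 0.21) and the membrane protease St14 (-1.65 ± 0.27, although 0.29 in XGFP). Of 30 genes of epithelial junctions and keratins, 7 fell and none rose (8 and none adjusted over the list alone). Epithelial genes ranked lower as a list (median -0.67, camera adjusted p = 2.33e-14, and adjusted p = 0.00146 with an estimated correlation). Other falls were Smpdl3a (-3.80 ± 0.99, 3 of 11 type 4 and 7 of 9 type 2 arrays) and the glutamate transporter Slc1a3 (-3.56 ± 0.98, 4 of 11 type 4 and 8 of 9 type 2 arrays).

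Among the rises were Nos3, the endothelial nitric oxide synthase (3.20 ± 0.41, adjusted p = 1.31e-05), the myosin-binding protein Mybpc3 (3.47 ± 0.66, 10 of 11 type 4 and 4 of 9 type 2 arrays), and the kinase Mapk10 (3.20 ± 0.91, 10 of 11 type 4 and 4 of 9 type 2 arrays). The iron carrier transferrin, Trf (2.94 ± 0.73, 8 of 9 type 2 arrays), and the vesicular nucleotide transporter Slc17a9 (3.05 ± 0.69, 4 of 9 type 2 arrays) rose too. Similar rises were those of Tnfsfm13 (3.09 ± 0.52, 6 of 9 type 2 arrays), Sytl3 (2.96 ± 0.49, 7 of 9 type 2 arrays), Rufy3 (2.99 ± 0.87, 9 of 11 type 4 and 3 of 9 type 2 arrays), Ceacam16 (3.21 ± 0.72, 6 of 9 type 2 arrays) and Matn1 (2.80 ± 0.62, 6 of 9 type 2 arrays). Ascl2 rose by 2.85 ± 0.67 (8 of 9 type 2 arrays), with 7.16 in XGFP and -0.37 in EGFP-TS3.5. Of 27 interferon response genes, 3 fell and none rose (4 and none adjusted over the list alone), among them Ifi27 (-3.51 ± 0.54, 10 of 11 type 4 arrays). Interferon genes ranked lower as a list (median -0.49, camera adjusted p = 2.2e-06, and adjusted p = 0.0193 with an estimated correlation). Of 23 stem cell genes 1 rose, Nr0b1 (1.57 ± 0.24, -0.38 in XGFP), and Zic3 (-1.85 ± 0.39, 8 of 11 type 4 arrays, 1.00 in EGFP-TS3.5) and Sox21 (-1.02 ± 0.27, 0.27 in XGFP) fell, with the same counts adjusted over the list alone. Stem cell genes ranked lower as a list (camera adjusted p = 0.0188, but adjusted p = 0.156 with an estimated correlation). Cdx2 (0.33 ± 0.31), Eomes (-0.41 ± 0.21), Esrrb (0.37 ± 0.29) and Sox2 (-0.15 ± 0.17) were not called. Nor were Elf5 (-0.52 ± 0.13), Hand1 (0.56 ± 0.16), Tfap2c (0.52 ± 0.20), Fgfr2 (-0.28 ± 0.21), Prl3d1 (1.52 ± 0.88, 9 of 11 type 4 and 6 of 9 type 2 arrays), Gcm1 (0.56 ± 0.25), Syna (0.50 ± 0.75, 5 of 11 type 4 and 4 of 9 type 2 arrays) and Col1a1 (0.17 ± 0.75, 10 of 11 type 4 and 6 of 9 type 2 arrays). Of 12 endothelial genes, 3 rose, Robo4 (1.25 ± 0.36), Plvap (1.13 ± 0.30) and Eng (1.11 ± 0.25), and none fell (the same adjusted over the list alone). Each had the opposite sign in XGFP. The list was not called (camera adjusted p = 0.0865).

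Mitosis and glycolysis genes ranked higher again and CDK inhibitors and cholesterol genes lower (camera adjusted p = 0.00802, 0.00118, 0.00257 and 0.00142). Each call was lost, with adjusted p = 0.213 for mitosis and DNA replication, 0.183 for CDK inhibitors and p53 targets, 0.277 for cholesterol synthesis and 0.249 for glycolysis and hypoxia with an estimated correlation. Fibroblast genes ranked lower (median -0.75, camera adjusted p = 0.00121, but adjusted p = 0.221 with an estimated correlation). Actin, SRF and YAP targets ranked lower too (median -0.37, adjusted p = 0.0231, but adjusted p = 0.435 with an estimated correlation). Their members Thbs1 (-3.13 ± 0.60, 6 of 11 type 4 arrays) and Ccn2 (-1.68 ± 0.46), matrix genes, fell. In total, 604 genes were called, 310 higher and 294 lower in type 4 (174 and 378 with quantile scaling), and of these 241 and 217 had the same sign in all 3 lines. EGFP-TS3.5 and XGFP differed in direction more often than chance gives, with 110 genes called in opposite directions where 45 were expected. B6TS4 and EGFP-TS3.5 shared 40 falls where 9.51 were expected. With slide as a block in B6TS4 and XGFP 1442 genes were called against 962 without it, and within single slides 1819 in XGFP (4 against 3 arrays) and 1688 in B6TS4, where type 4 was that 1 dimmest array against 2. The count was 322 and 384 without B6TS4 type 2 replicates 1 and 2, and 1034 without B6TS4 type 4 replicate 2.

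The ectoplacental cone was compared with the extraembryonic ectoderm (6 and 6 arrays, averaged over 2 strains) to give the differences between tissues against which the colonies could be read. Factors of the stem cell state fell in the cone. Esrrb fell by 7.29 ± 0.36 (adjusted p = 3.23e-17), Eomes by 4.39 ± 0.26, Cdx2 by 3.51 ± 0.39, Elf5 by 1.16 ± 0.16, Fgfr2 by 1.54 ± 0.26 and the signalling protein Bmp4 by 7.81 ± 0.33. Sox2 was at least 333-fold lower, not well above background on any cone array. Nr0b1 (-11.30 ± 0.30, 3 of 6 EPC arrays) and Zic3 (-9.31 ± 0.48, 3 of 6 EPC arrays) fell too. Tfap2c (1.16 ± 0.25), Gata3 (1.69 ± 0.29), Ets2 (1.01 ± 0.26) and Rhox6 (1.33 ± 0.38), of the same list, rose. Of 23 stem cell genes, 4 rose and 12 fell (4 and 13 adjusted over the list alone). Stem cell genes ranked lower as a list (median -1.49, camera adjusted p = 4.54e-37, and adjusted p = 0.000256 with an estimated correlation). Of 21 targets of FGF and ERK, 3 rose and 12 fell (3 and 13 adjusted over the list alone). The feedback inhibitors Dusp6 (-7.72 ± 0.39) and Spry1 (-5.26 ± 0.32) fell, and Fosl1 (3.25 ± 0.50) and Myc (2.05 ± 0.23) rose. FGF and ERK targets ranked lower as a list (median -1.76, camera adjusted p = 1.83e-19, and adjusted p = 0.0193 with an estimated correlation).

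Giant cell genes were among the rises in the cone. Of 19, 13 rose and 1 fell (the same adjusted over the list alone). The lactogens Prl3d1 (7.39 ± 1.10, 5 of 6 ExE arrays), Prl3d2 (7.92 ± 1.27, 4 of 6 ExE arrays), Prl2a1 (8.34 ± 0.93, 1 of 6 ExE arrays) and Prl7a1 (7.76 ± 0.70, 2 of 6 ExE arrays) rose, and the circadian factor Bhlhe40 (-2.26 ± 0.35) fell. Giant cell genes ranked higher as a list (median 4.70, camera adjusted p = 2.25e-07, but adjusted p = 0.0574 with an estimated correlation). Of 20 genes of the ectoplacental cone and spongiotrophoblast, 8 rose and 3 fell (9 and 3 adjusted over the list alone). Among them Plac8 (4.92 ± 0.59), Ascl2 (3.12 ± 0.83) and Tpbpb (3.36 ± 0.68, 5 of 6 EPC and 1 of 6 ExE arrays) rose, and the VEGF receptor Flt1 (-3.31 ± 0.48, 5 of 6 EPC arrays) fell. The list was not called (camera adjusted p = 0.0977). Nor was that of 18 syncytiotrophoblast genes, with 2 rises and 1 fall (the same adjusted over the list alone, adjusted p = 0.999, test down with a median of 0.13). Hand1 rose by 2.41 ± 0.20, while Gcm1 differed by 0.75 ± 0.31, Syna by -0.34 ± 0.93 (3 of 6 EPC and 3 of 6 ExE arrays) and Col1a1 by -1.23 ± 0.93 (5 of 6 ExE arrays). Entpd1, an ecto-nucleotidase of vessels and immune cells, rose by 10.16 ± 0.57 (3 of 6 ExE arrays), and Cdh5, the adhesion molecule VE-cadherin, by 9.41 ± 1.03 (4 of 6 ExE arrays). Serpinb9g rose by 8.81 ± 1.36 (4 of 6 ExE arrays) and Spn, a leukocyte surface protein, by 8.04 ± 1.00 (5 of 6 ExE arrays), and Ms4a6d was at least 65.2-fold higher. The protease inhibitors Serpinb9c (8.33 ± 1.17, 2 of 6 ExE arrays), Serpinb9e (8.46 ± 1.23, 4 of 6 ExE arrays) and Serpinb9f (8.49 ± 1.34, 4 of 6 ExE arrays) and the globin Hbb-bt (7.96 ± 0.88, 5 of 6 EPC and 1 of 6 ExE arrays) were among the largest rises. Keratins Krt7 (5.10 ± 0.42) and Krt8 (3.06 ± 0.38) rose while claudins Cldn6 (-3.06 ± 0.26) and Cldn3 (-2.51 ± 0.33), and Cdh1 (-2.15 ± 0.27, but -0.13 in B6) fell. The epithelial list, with 8 rises and 6 falls of 30 (the same adjusted over the list alone), was not called (camera adjusted p = 0.812, median -0.08 and mean 0.13, the test on the side of the mean).

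Interferon response genes rose, 16 of 27 with none lower (17 and 1 adjusted over the list alone). They were led by Rtp4 (7.36 ± 1.19, 4 of 6 ExE arrays) and Rsad2 (6.08 ± 0.80, 1 of 6 ExE arrays). Interferon genes ranked higher as a list (median 1.64, camera adjusted p = 7.13e-06, and adjusted p = 0.0193 with an estimated correlation). Genes of pluripotency and the epiblast were lower in the cone, 12 of 19 with 1 higher (the same adjusted over the list alone). They included the mesoderm factor T (-9.22 ± 0.90, 3 of 6 EPC arrays), Fgf5 (-6.91 ± 1.34, 2 of 6 EPC arrays) and Pou5f1 (-5.49 ± 0.62, 5 of 6 EPC arrays). The neural and embryonic factor Sox3 (-11.86 ± 0.60, 3 of 6 EPC arrays) and the retinoic acid hydroxylase Cyp26a1 (-9.16 ± 1.09, 3 of 6 EPC arrays) fell as well. Other large falls were Trim9 (-9.06 ± 0.34, 1 of 6 EPC arrays), the neurotrophin Ntf3 (-8.94 ± 0.59, 1 of 6 EPC arrays), the neuroendocrine factor Insm1 (-8.55 ± 0.40, 2 of 6 EPC arrays) and Tceal3 (-8.52 ± 1.14, 2 of 6 EPC arrays). That list ranked lower (median -1.69, camera adjusted p = 3.77e-15, and adjusted p = 0.00546 with an estimated correlation). Leukocyte and blood genes, markers of another cell type, moved with the cone, 9 of 20 higher and none lower (10 and none adjusted over the list alone, camera adjusted p = 0.00121, but adjusted p = 0.183 with an estimated correlation). The globin Hba-a1 was at 9.85 in ICR and 2.49 in B6. Of 21 activin, nodal and BMP genes, 4 rose and 8 fell (4 and 9 adjusted over the list alone), such as Smad6 (-4.03 ± 0.32) and Id2 (-3.45 ± 0.17). They ranked lower (camera adjusted p = 1.05e-05, but adjusted p = 0.127 with an estimated correlation). Of 18 Wnt targets, 2 rose and 4 fell (the same adjusted over the list alone), such as Axin2 (-6.05 ± 0.51, 3 of 6 EPC arrays). They ranked lower (camera adjusted p = 0.0456, but adjusted p = 0.307 with an estimated correlation). Oxidative phosphorylation ranked higher with no called member of 31, also adjusted over the list alone (median 0.40, adjusted p = 0.00296, but adjusted p = 0.307 with an estimated correlation). CDK inhibitors and p53 targets ranked lower with 2 higher and 5 lower of 24 (the same adjusted over the list alone, adjusted p = 0.0143, but adjusted p = 0.307 with an estimated correlation). Decidual genes, which maternal tissue would carry, had 3 higher and 3 lower of 17 (4 and 3 adjusted over the list alone, camera adjusted p = 0.49).

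In total, 2865 genes were called between the tissues, 1447 higher and 1418 lower in the cone. Of these, 1374 and 1385 had the same sign in both strains. The strains called 1594 genes in B6 and 2984 in ICR, sharing 452 rises where 75.4 were expected and 583 falls where 68.3 were expected (correlation across genes 0.616). The cone and ectoderm differed by strain in 661 genes. Both tissues of a strain were on 1 slide, so slide cannot account for a difference within a strain. Strain, slide and scan day cannot be told apart. Scaling by the median of probes well above background, which moved the median of all genes from 0.17 to 0.77, gave 3696 rises and 782 falls.

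**Figure D3:**
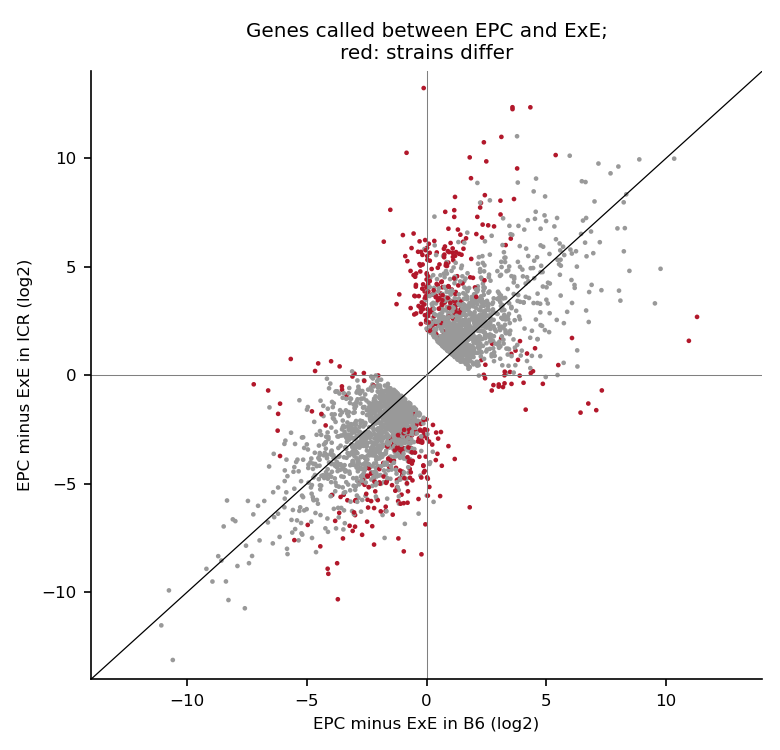
Each point is a gene called between cone and ectoderm, with its log2 difference in B6 on the horizontal axis and in ICR on the vertical axis. Red points are among the 661 genes whose difference varied by strain, and the line marks equal differences.

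The colonies were placed between the tissues by a score. It was the mean of 1675 genes higher in the cone minus that of 1661 genes higher in the ectoderm, chosen on the 12 tissue arrays alone. Group means were -1.58 in B6 ExE, -1.21 in ICR ExE, 2.30 in B6 EPC and 4.22 in ICR EPC, and every colony group lay between -1.45 and 0.09. Type 4 colonies scored 0.39 above type 1 (exact permutation p = 0.00133, two-sided, 42875 splits within lines). Type 2 colonies scored 0.26 above type 1 (exact permutation p = 0.000571, 10500 splits), with 0.06 in B6TS4 (p = 0.333, exact), 0.48 in EGFP-TS3.5 (p = 0.1, exact) and 0.22 in XGFP (p = 0.0286, exact). Type 4 differed from type 2 by 0.14 (exact permutation p = 0.277), an average of -0.45 in EGFP-TS3.5 and 0.77 in XGFP (each exact permutation p = 0.0286) and 0.09 in B6TS4 (p = 0.5, exact). By line the difference between types 4 and 1 was 0.99 in XGFP (exact permutation p = 0.0286, the smallest its 35 splits allow), 0.15 in B6TS4 (p = 0.114, exact) and 0.03 in EGFP-TS3.5 (p = 0.629, exact). The difference between lines in this score was not itself tested. Type and slide cannot be told apart in EGFP-TS3.5. With slide as a block it was 0.98 in XGFP, through 1 type 2 array that links the slides, and 0.09 in B6TS4, from 1 type 4 array. The defined line scored lower than type 1 colonies of EGFP-TS3.5 and XGFP, with a difference of -0.45 (exact permutation p = 0.0119, the smallest its 84 splits allow). In a second score, genes called between types 4 and 1 in 2 lines were measured in the line left out. Types 4 and 1 differed in it by 0.87 in B6TS4 (exact permutation p = 0.0286, the smallest possible), 0.48 in EGFP-TS3.5 (p = 0.143, exact) and 0.04 in XGFP (p = 0.771, exact). On the genes called in B6TS4 alone, the defined line scored -1.38 against type 1 (exact permutation p = 0.0119). Against type 1 of EGFP-TS3.5 and XGFP, type 2 scored -0.57 (p = 0.00143, exact) and type 4 0.99 (p = 0.0171, exact). The latter lay in EGFP-TS3.5 (means 0.90 and -0.99), where slide goes with type, and not in XGFP (-0.45 and -0.53).

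**Figure D4:**
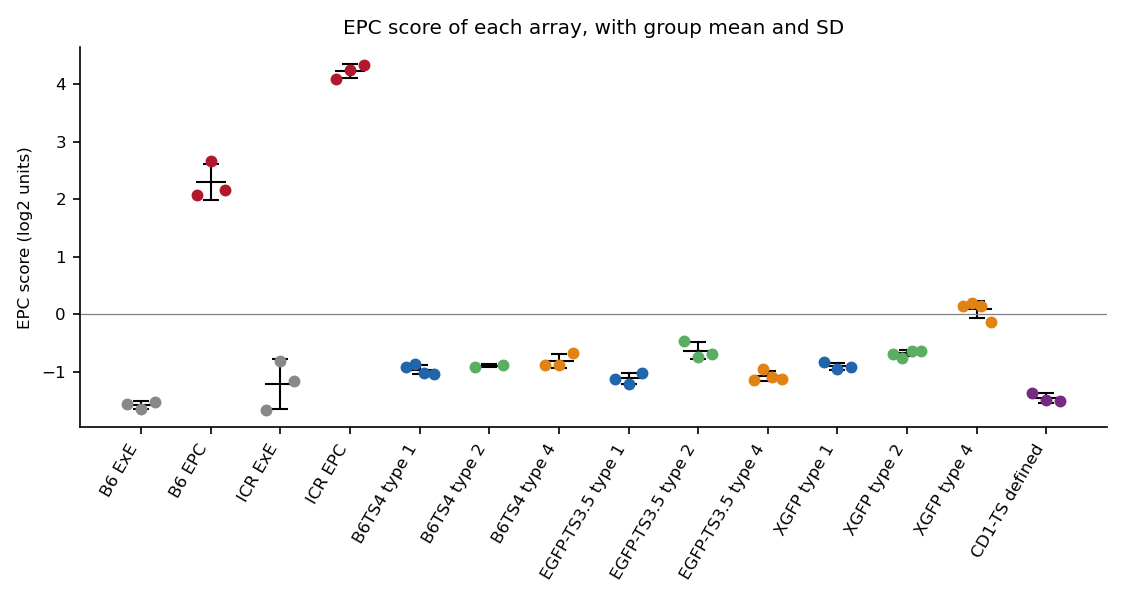
Each point is the cone score of 1 array in log2 units, by group, with the group mean and SD. The 12 tissue arrays set the ends, ExE with group means of -1.58 and -1.21 and EPC with 2.30 and 4.22. The XGFP type 4 group, with a mean of 0.09, is the highest of the colony groups.

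The CD1-TS line in defined medium was compared with type 1 colonies of EGFP-TS3.5 and XGFP (3 and 6 arrays), to show what goes with culture in defined medium. These conventional lines had the same strain label, and line and medium differed together. Mesenchymal genes were lower in the defined line. Vim, the intermediate filament vimentin, fell by 7.27 ± 1.10 (adjusted p = 3.53e-05, 1 of 3 defined arrays) and Twist2 by 6.30 ± 1.15 (1 of 3 defined arrays, adjusted p = 0.00042). Twist1 fell by 1.86 ± 0.60 and the integrin Itgb3 by 1.78 ± 0.41. Of 18 genes of mesenchymal transition, 5 fell and none rose (6 and none adjusted over the list alone). Mesenchymal genes ranked lower as a list (median -1.56, camera adjusted p = 3.94e-05, and adjusted p = 0.0101 with an estimated correlation). Of 29 fibroblast genes 1 rose and 4 fell (1 and 5 adjusted over the list alone), and they ranked lower too (camera adjusted p = 0.0231, but adjusted p = 0.393 with an estimated correlation). Loxl1 was at least 9.28-fold lower and Col1a1 differed by -1.64 ± 1.14 (1 of 3 defined arrays). Other losses were of at least 253-fold for the peptide transporter Slc15a2, 71.8-fold for the matrix protease Adamts1 and 73-fold for the kinase Sik1, none well above background on a defined array. The cell cycle kinase Cdk2 fell by 6.66 ± 0.33 (1 of 3 defined arrays), the kallikrein Klk1b22 by 7.85 ± 0.48 (1 of 3 defined arrays) and Rab3il1 by 6.38 ± 0.88 (1 of 3 defined arrays), and Klk1b27 and Blnk were at least 35-fold and 25.9-fold lower. Cdkn1c, a CDK inhibitor expressed from the maternal allele, rose by 5.55 ± 0.77 (3 of 6 type 1 arrays), with 10.62 against XGFP and 0.48 against EGFP-TS3.5.

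Among single genes higher in the defined line, Lefty1, an inhibitor of nodal, was at least 20.3-fold higher, the homeobox gene Evx1 at least 58.6-fold, the nuclear receptor gene Nr1h5 at least 357-fold and Ednra at least 29.4-fold, none well above background on a type 1 array. Lefty2 rose by 4.13 ± 0.82 (3 of 6 type 1 arrays) and the endoderm factor Sox17 by 5.24 ± 1.55 (1 of 6 type 1 arrays). T rose by 3.85 ± 1.11 (5 of 6 type 1 arrays) and the protease Ctsk by 7.10 ± 1.54 (3 of 6 type 1 arrays). Rab25, a regulator of epithelial traffic, rose by 5.09 ± 0.96 (2 of 6 type 1 arrays), Gdpd3 by 10.69 ± 1.70 (1 of 6 type 1 arrays) and Rab38 by 6.17 ± 0.94 (1 of 6 type 1 arrays). Lower bounds were 53.9-fold for Lypd10, 56.2-fold for Aldh3b1, 24.7-fold for Radx and 14.6-fold for Armcx1, all higher. Sox2 (1.02 ± 0.26) rose, Gata3 (-1.42 ± 0.36) and Hand1 (-1.13 ± 0.24) fell. Cdx2 (0.02 ± 0.48), Eomes (0.53 ± 0.31), Elf5 (0.39 ± 0.20) and Esrrb (0.16 ± 0.45) did not pass the test. Neither did Tfap2c (-0.44 ± 0.31), Fgfr2 (0.03 ± 0.32), Ascl2 (-0.29 ± 1.02), Prl3d1 (1.32 ± 1.35, 2 of 6 type 1 arrays), Gcm1 (0.08 ± 0.38) and Cdh1 (0.24 ± 0.33), and Syna was well above background on 1 of 6 type 1 arrays and no defined array. Of 21 activin, nodal and BMP genes 3 rose and 3 fell (camera adjusted p = 0.944). Id1 (-1.78 ± 0.40) and Id3 (-3.41 ± 0.73, 1 of 3 defined arrays) fell. Of 18 syncytiotrophoblast genes none rose and 3 fell (1 and 5 adjusted over the list alone), such as Tfeb (-1.48 ± 0.32). They ranked lower (camera adjusted p = 0.016, but 0.188 with an estimated correlation). Of 27 interferon genes 3 fell and none rose (the same adjusted over the list alone), such as Ifi27 (-5.51 ± 0.83, 1 of 3 defined arrays). They ranked lower (camera adjusted p = 0.000141, but 0.0574 with an estimated correlation). Of 30 imprinted genes 6 rose and none fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0989).

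Lists of other cell types ranked lower too. Of 12 endothelial genes 2 fell and none rose (3 and none adjusted over the list alone), such as Esam, at least 16.1-fold lower. Camera gave adjusted p = 0.0141, but adjusted p = 0.156 with an estimated correlation. Of 17 decidual genes 2 fell and none rose (3 and none adjusted over the list alone, camera adjusted p = 0.0284, but adjusted p = 0.0747 with an estimated correlation). Actin, SRF and YAP targets ranked lower with 2 falls of 18 (2 adjusted over the list alone), such as Csrp1 (-1.95 ± 0.40). Camera gave adjusted p = 0.00826, but adjusted p = 0.307 with an estimated correlation. Glycolysis and hypoxia genes ranked lower with 1 rise and 1 fall of 26 (1 and 2 adjusted over the list alone). Camera gave adjusted p = 0.0395, but adjusted p = 0.467 with an estimated correlation. In total, 1113 genes were called, 594 higher and 519 lower in the defined line (1021 and 124 with the median scaling, 663 and 870 with normexp), and 1693 against XGFP alone. With slide as a block, possible only against XGFP, 226 genes were called. No type 1 array shared a slide with the defined arrays, and the block linked them to XGFP type 1 through XGFP type 2.

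Type 1 colonies were compared with the ectoderm of the same strain (10 and 6 arrays) to show how cultured stem cells differ from their tissue. The core factors were not called between colonies and tissue, with Cdx2 at 0.46 ± 0.35, Eomes at 0.28 ± 0.23, Esrrb at 0.37 ± 0.33, Tfap2c at 0.24 ± 0.23, Elf5 at -0.46 ± 0.15 and Fgfr2 at -0.16 ± 0.23. In B6 alone Cdx2 (1.58) and Esrrb (1.51) were called, against -0.65 and -0.76 in ICR. Cdh1 (0.53 ± 0.24), Gcm1 (0.05 ± 0.28) and Syna (-0.62 ± 0.84, 5 of 10 type 1 and 3 of 6 ExE arrays) were not called either, and Prl3d1 (-3.64 ± 0.99, 6 of 10 type 1 and 5 of 6 ExE arrays) fell. Of 30 epithelial genes 11 fell, such as Cldn7 (-4.57 ± 0.41), and none rose (the same adjusted over the list alone), though the list was not called (camera adjusted p = 0.06). Sox2 (1.55 ± 0.19) and Hand1 (1.40 ± 0.18) rose. CDK inhibitors and p53 targets rose, 15 of 24 with 2 lower (16 and 2 adjusted over the list alone). The rises were led by Cdkn1a (4.21 ± 0.45, adjusted p = 7.5e-09), Plk2 (4.06 ± 0.38), Btg2 (3.96 ± 0.18) and the tumour suppressor Cdkn2a (3.46 ± 0.85, 4 of 6 ExE arrays), and Cdkn2c (-1.80 ± 0.63) and Cdkn1c (-2.61 ± 0.57, 7 of 10 type 1 arrays, although 0.28 in B6) fell. The list ranked higher (median 2.23, camera adjusted p = 7.63e-22, and adjusted p = 0.000544 with an estimated correlation). Of 35 genes of mitosis and DNA replication, 6 fell and none rose (the same adjusted over the list alone), such as Plk1 (-1.14 ± 0.16) and Mcm5 (-1.20 ± 0.21). Mitosis genes ranked lower as a list (median -0.41, camera adjusted p = 0.00802, but adjusted p = 0.2 with an estimated correlation). Interferon genes rose, 10 of 27 with none lower (11 and none adjusted over the list alone), such as Parp14 (5.84 ± 0.36) and Ifih1 (3.25 ± 0.39). Interferon genes ranked higher as a list (median 1.14, camera adjusted p = 5.44e-07, and adjusted p = 0.0193 with an estimated correlation).

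Some mesenchymal and fibroblast genes were higher in the colonies, which grew on feeder fibroblasts. Twist2 rose by 6.00 ± 0.85 (1 of 6 ExE arrays), Vim by 4.49 ± 0.81 (5 of 6 ExE arrays), S100a4 by 5.31 ± 0.81 (5 of 6 ExE arrays) and Fbln2 by 4.92 ± 0.48 (4 of 6 ExE arrays), while Col1a1 differed by 1.52 ± 0.84 (5 of 6 ExE arrays). Of 18 genes of mesenchymal transition 10 rose and 1 fell, Snai1 (-1.58 ± 0.37) (the same adjusted over the list alone, camera adjusted p = 0.00574, but adjusted p = 0.0574 with an estimated correlation). Of 29 fibroblast genes 12 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.000182, but adjusted p = 0.179 with an estimated correlation). Of 19 immediate early genes 7 rose and 1 fell (the same adjusted over the list alone), with rises of Jun (2.87 ± 0.48, 5 of 6 ExE arrays) and Atf3 (2.05 ± 0.41). They ranked higher (camera adjusted p = 0.000124, but adjusted p = 0.295 with an estimated correlation). Of 21 FGF and ERK targets 8 rose and 1 fell (the same adjusted over the list alone), with rises of Egr1 (1.95 ± 0.67) and Ccnd1 (1.72 ± 0.31). They ranked higher too (camera adjusted p = 0.00924, but adjusted p = 0.283 with an estimated correlation). Of 12 endothelial genes 4 rose and 1 fell (the same adjusted over the list alone), with a rise of the VEGF receptor Kdr (3.59 ± 0.29). They ranked higher (camera adjusted p = 0.013, but adjusted p = 0.188 with an estimated correlation). Actin, SRF and YAP targets ranked higher, with 3 higher and none lower of 18 (the same adjusted over the list alone, camera adjusted p = 0.0341, but adjusted p = 0.467 with an estimated correlation).

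Genes of pluripotency and the epiblast were lower in the colonies than in the ectoderm, 11 of 19 with 2 higher (the same adjusted over the list alone). They included Otx2 (-6.14 ± 0.85, 5 of 10 type 1 arrays), Pou5f1 (-5.83 ± 0.56, 6 of 10 type 1 arrays) and Dppa5a (-5.52 ± 0.43, 8 of 10 type 1 arrays), while Nanog (1.46 ± 0.30) rose. Epiblast genes ranked lower as a list (median -1.56, camera adjusted p = 0.00107, but adjusted p = 0.213 with an estimated correlation). Of 26 glycolysis and hypoxia genes 1 rose and 8 fell (the same adjusted over the list alone), with a fall of Slc2a3 (-5.78 ± 0.34). They ranked lower (camera adjusted p = 0.000182, but adjusted p = 0.237 with an estimated correlation). Oxidative phosphorylation ranked lower with no called member of 31, also adjusted over the list alone (adjusted p = 0.0483, but adjusted p = 0.603 with an estimated correlation). Ascl2 (-4.35 ± 0.75), Plac8 (-6.26 ± 0.53, 6 of 10 type 1 arrays) and the noncoding imprinted gene Meg3 (-6.82 ± 0.59, 9 of 10 type 1 arrays) fell. Of 30 imprinted genes, 3 rose and 9 fell (the same adjusted over the list alone), such as Snrpn (-6.10 ± 0.42, 6 of 10 type 1 arrays). The list was not called (camera adjusted p = 0.47). Large rises elsewhere were the kallikrein Klk1b22 (7.24 ± 0.36, 2 of 6 ExE arrays), the growth factor Gdf6 (7.08 ± 0.52, 4 of 6 ExE arrays), Wt1 (6.71 ± 0.63, 4 of 6 ExE arrays), Wnt9a (6.06 ± 0.44, 4 of 6 ExE arrays) and the placental homeobox gene Esx1 (5.69 ± 0.55, 5 of 6 ExE arrays). Klk1b27 rose by 5.96 ± 0.38 (2 of 6 ExE arrays), and the secreted phosphoprotein Spp1 and the vesicular transporter Slc32a1 were at least 15-fold and 14-fold higher. Large falls were Ldoc1 (-8.41 ± 0.82, 8 of 10 type 1 arrays), Fmr1nb (-7.92 ± 0.45, 9 of 10 type 1 arrays), Vrtn, at least 143-fold, and the magnesium channel Trpm6, at least 71.5-fold. Radx (-8.07 ± 0.67, 4 of 10 type 1 arrays), Grm6 (-7.14 ± 0.79, 2 of 10 type 1 arrays), Zfp59 (-7.05 ± 0.68, 6 of 10 type 1 arrays) and Zfp105 (-6.94 ± 0.98, 5 of 10 type 1 arrays) fell too, and Mcf2 was at least 34.7-fold lower.

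In total, 3484 genes were called, 1559 higher and 1925 lower in the colonies. This balance turned with strain (2251 and 1794 in B6, 1158 and 2807 in ICR) and scaling (3009 and 481 with the median scaling). Of these, 1420 and 1845 had the same sign in both strains. No ectoderm array shared a slide with a type 1 array. With slide as a block, which links them only through other groups (B6TS4 type 4, and XGFP type 2 with the defined line), 1031 genes were called.

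**Figure D5:**
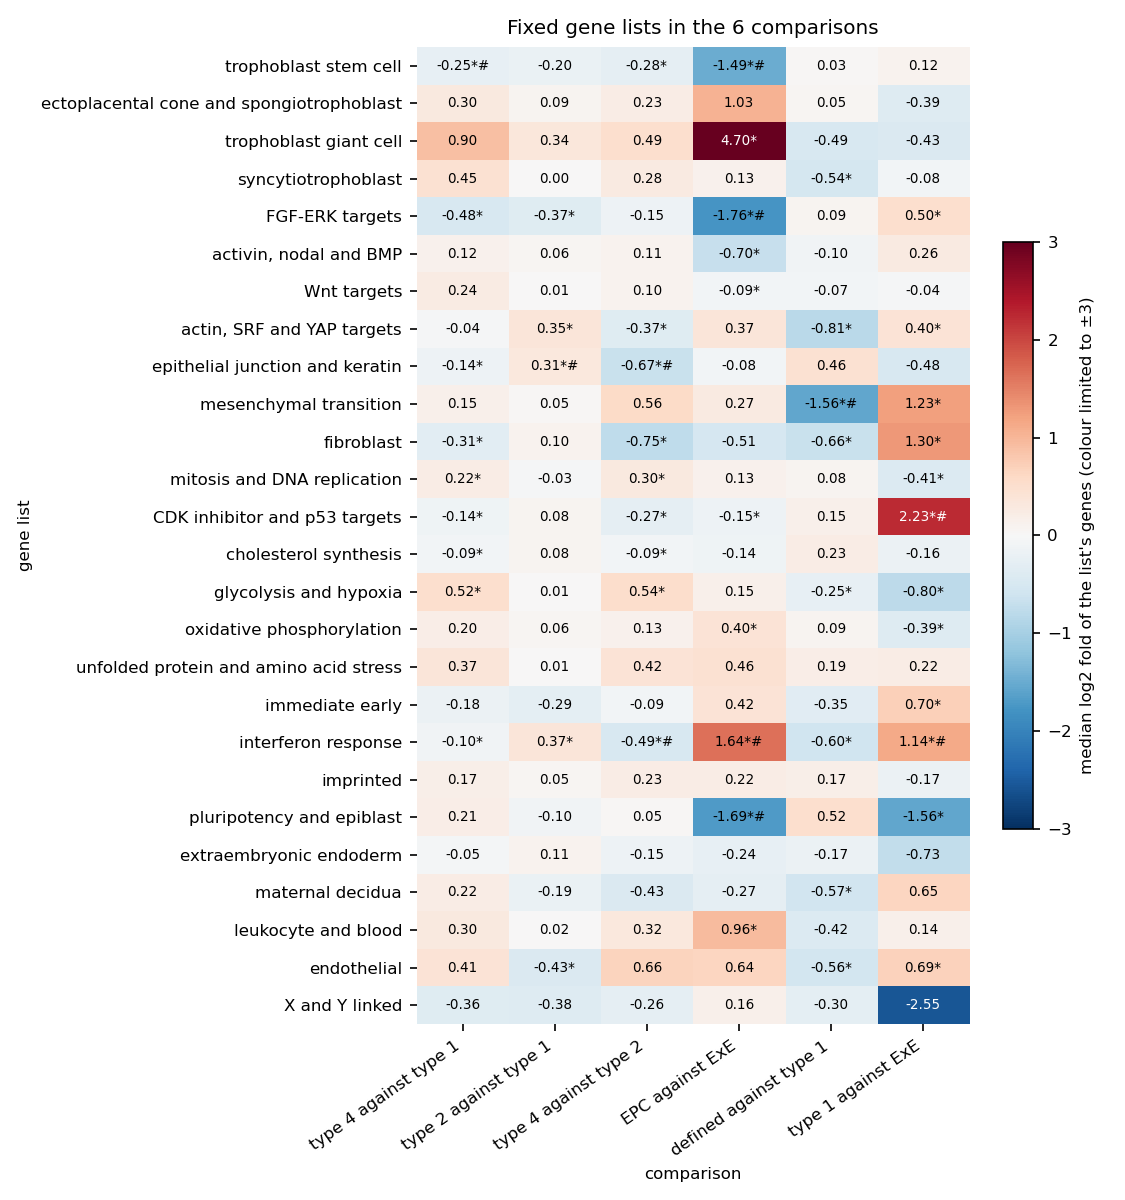
Colour gives the median log2 fold change of each of the 26 fixed lists in each of the 6 comparisons, limited to 3 in either direction. A star marks the 53 of 156 tests called by camera, and a hash mark the 11 of them also called with an estimated correlation.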

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

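The tests of signal level, of the mesenchymal and imprinted genes, of single arrays far from their group and of other splits of the samples were chosen only after the result was seen. The tests of slide and of a wrong array for the difference between lines were set before it.

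Type 4 minus type 1 differed between the lines in 2677 genes (limma, adjusted p under 0.05), with Epc2 (adjusted p = 3.21e-07) at -0.98 in B6TS4, -0.80 in EGFP-TS3.5 and 3.91 in XGFP. In the same order Zbtb2 (adjusted p = 6.73e-07) was at -0.54, -0.30 and 2.08, Vmn2r26 at -0.59, 6.47 and 0.56, Ripk4 at -1.64, -1.37 and 1.43 and Lrba at -2.20, -1.25 and 1.24 (each adjusted p = 8.29e-07). Those were the smallest p. Chance is not firmly excluded at 0.05, as 3 of 100 drawn splits, the real one included, gave 2677 genes or more. The highest other split gave 3510, more than the real one, and put the 3 B6TS4 arrays with a 75th percentile under 500 on 1 side, which points to a structure of the samples beside colony type.

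The count was 1930 with quantile scaling, 158 with the median scaling, 1361 with the replicate block and 1382 with slide as a random block, and the cause was not tested. With log2 of each array's 75th percentile as a covariate 2942 genes were called, and 2863 without arrays under 500, which argues against signal level as the whole cause. A wrong sample on EGFP-TS3.5 type 1 replicate 2 is argued against too, since B6TS4 and XGFP, which do not use that array, differed in 2163 genes. With a slide block they differed in 425 genes, between the bounds set for slide as cause and not, so slide cannot be told apart for part of the pattern, although 2126 of the 2163 genes kept their sign and 331 were called in both. Differences between the lines themselves, in strain of origin or in what each line forms as type 4 colonies, stay open and were not tested.

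Mesenchymal genes were lower in the defined line than in type 1 colonies. Feeder fibroblast RNA in those colonies cannot be told apart as a source. Of 3 abundant collagens Col1a1 (-1.64 ± 1.14, Vim -7.27) was well above background on 6 of 6 type 1 arrays. Col1a2 was on 1 and Col3a1 on 0. Yet the fibroblast list, which shares Twist2, ranked lower. Slide cannot be told apart either. Against XGFP the median of 18 genes was -1.58 without and -2.58 with a slide block, within 2 of a gene's median SE (1.69). Vim (-12.16 ± 2.29) and Twist2 (-8.44 ± 2.75) lay further from 0 with it, but through 1 linking array, XGFP type 2 replicate 1, whose own Vim was -3.47. Line and medium cannot be told apart, because 1 line grew in defined medium, and an effect of the medium alone was not tested.

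Maternally expressed imprinted genes were low in XGFP beside EGFP-TS3.5 over the colony types, with Phlda2 at -10.88 ± 0.58 (4 of 11 XGFP arrays), Cdkn1c at -9.06 ± 0.48 (3 of 11), Slc22a18 at -6.34 ± 0.54 (4 of 11) and Igf2r at -4.20 ± 0.23 (limma, of 2834 genes called between the lines, 1039 were lower). Of 15 maternally expressed genes 12 were lower, 8 of them called, and Asb4 (1.26 ± 0.22, 7 of 11 XGFP and 3 of 10 EGFP-TS3.5 arrays) and Dcn (2.10 ± 0.75, 4 of 11 and 1 of 10) were called higher. Of 14 paternally expressed genes 5 were lower, 3 of them called, such as Dlk1 (-7.88 ± 0.53, 4 of 11 XGFP arrays), and 6 were called higher, such as Peg3 (1.08 ± 0.26). Slide is argued against, since within slide 5 the median was -2.02 over 14 maternally expressed genes, 12 of them lower, and -0.0690 over 14 paternally expressed genes, 8 of them lower. A lowering in XGFP that follows the expressed parental allele cannot be told from one of single genes on either allele. The means (-2.62 and -0.16) gave an exact permutation p (two-sided, genes as independent) of 0.0482 over all genes. It was 0.0750 over the 19 well above background on every EGFP-TS3.5 array.

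EPC minus ExE differed between the strains in 661 genes. Chance can be excluded for this count, since no other of 100 splits gave as many, the highest being 134. The smallest p were those of Il1b (adjusted p = 1.90e-09), at -0.29 in B6 and 6.17 in ICR, and of Tmem121 (-4.13 and -8.92) and Cxadr (1.18 and -3.86), each with adjusted p = 5.91e-08. Gata1 (1.80 and -6.09) and Sirpb1b (-0.04 and 5.76) followed (each adjusted p = 1.16e-07). Strain, slide and scan day cannot be told apart.

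Chance can also be excluded for the counts of 4 comparisons, in each of which 1 of 100 splits, the real one, gave as many genes. The real counts and the highest other split were 744 and 563 between types 4 and 1, 604 and 542 between types 4 and 2, 2865 and 1789 between EPC and ExE, and 3484 and 1772 between type 1 colonies and ExE. For the defined line chance can be excluded at 0.05, as 3 of 84 splits gave the 1113 genes or more, but the highest, 1750, set XGFP type 1, all on slide 5, against the rest, so line or slide gave as many (226 against XGFP with slide as a block). Chance cannot be excluded for the 35 genes between types 2 and 1, as 8 of 100 splits gave as many and the highest gave 162, several times the real count, which points to a structure other than colony type. That split did not follow slide, but put EGFP-TS3.5 type 1 replicate 2 with 2 type 2 arrays, with which it correlated at 0.419 and 0.426 (48 genes without it).

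XGFP type 4 replicate 4 had a cone score of -0.131, apart from 0.142 to 0.188 on the other arrays of its group. This was 1 of 19 tests, of 4 or 5 measures in each of the 4 groups of 4 arrays (gap to the nearest over whole range 0.858), and chance gives about 1 in 20. Of 16727 kept probes without a gene symbol, which no comparison of genes used, 750 were called between types 4 and 1 and 915 between EPC and ExE.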

How the results depend on the processing

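Normexp on the median signal, slide as a random block, the signal level covariate, the blocks and averages over B6TS4 and XGFP or against XGFP alone, the replaced column and the omission of dim arrays were tests chosen only after the result was seen. For the values below the cause was not tested, except that fewer probes, samples or lines, or no fold minimum, change a count by construction. Scaled to the median of probes well above background, 141 genes were called between types 4 and 1, 8 between types 2 and 1, 129 between types 4 and 2, 4478 between EPC and ExE, 158 for line by type and 284 for strain by tissue. With normexp on the median signal 390 were called between types 4 and 1. That correction on the mean signal was not run, since the files hold none. Signal over background limits the faint genes: probes well above background on all arrays gave 262 genes between types 4 and 1, 257 between types 4 and 2, 11 between types 2 and 1, 1603 between EPC and ExE, 691 for the defined line, 1840 between type 1 and ExE and 430 for strain by tissue. Array weights gave 1653 between types 4 and 1, 96 between types 2 and 1, 1197 between types 4 and 2, 7031 for line by type and 1814 for strain by tissue. A fit of only the arrays compared gave 303 between types 4 and 2, 572 for the defined line, 1083 for line by type and 1019 for strain by tissue. Without the fold minimum 2352 genes were called between types 4 and 1, 1775 between types 4 and 2 and 6285 between type 1 and ExE. With replicate number as a block 435 were called between types 4 and 1, 12 between types 2 and 1 and 1361 for line by type. Numbers were not treated as pairs, as the own number matched best in 10 of 32 pairs. Slide as a fixed block gave 20 between types 2 and 1, and as a random block 23, with 1382 for line by type. Over B6TS4 and XGFP alone, slide as a block gave 297 between types 4 and 1, 1442 between types 4 and 2 and 1031 between type 1 and ExE, against 1331 and 962 for the first 2 without it, and 226 for the defined line against XGFP. Types 4 and 1, types 4 and 2 and line by type could not be fitted with slide as a block over all 3 lines. With arrays of a 75th percentile under 500 left out, 440 were called between types 4 and 1 and 313 between types 4 and 2, and without EGFP-TS3.5 type 1 replicate 2 as well, 75 between types 2 and 1 and 319 between types 4 and 2. Alone, EGFP-TS3.5 gave 204 and XGFP 2733 between types 4 and 1, XGFP 1881 between types 4 and 2, and B6TS4 9, EGFP-TS3.5 107 and XGFP 230 between types 2 and 1. B6 alone gave 1594 between EPC and ExE, and the defined line differed from XGFP type 1 in 1693.

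Leaving out each array in turn gave 494 to 1098 between types 4 and 1, 3 to 48 between types 2 and 1, 322 to 1034 between types 4 and 2, 2610 to 2803 between EPC and ExE, 745 to 1329 for the defined line, 3268 to 3582 between type 1 and ExE, 1923 to 4590 for line by type and 420 to 660 for strain by tissue. Counts moved by over 1.5 times without B6TS4 type 4 replicate 3 (494 between types 4 and 1), B6TS4 type 4 replicate 2 (1034 between types 4 and 2, 4590 for line by type), and B6TS4 type 2 replicates 1 and 2 (322 and 384 between types 4 and 2, 3 and 20 between types 2 and 1). Between types 2 and 1 they also did for the arrays named with that comparison, and for strain by tissue without B6 EPC replicate 3 (420), ICR ExE replicate 2 (420) and ICR EPC replicate 3 (430). In all alternatives but single lines the cone scores of colony types and the defined line kept direction and side of the threshold. The type axis of B6TS4 (0.87, permutation p = 0.0286) lost its call at 1.18 with the median scaling (permutation p = 0.0857), at 0.91 without the dim arrays (permutation p = 0.25), where fewer splits exist, and at 0.80 to 0.96 without single arrays of B6TS4 type 1 or 4, over a range of 0.53 to 0.96 for all arrays left out. That of EGFP-TS3.5 (0.48, permutation p = 0.143) passed at 0.78 from the value table, 0.75 with the table's column for the odd array, 0.68 without B6TS4 type 4 replicate 1 and 0.48 without XGFP type 1 replicate 1 (each permutation p = 0.0286), over a range of 0.18 to 0.72. That of XGFP had no call in any alternative, at -0.13 to 0.26 without single arrays. Of 53 gene list calls 11 held with an estimated correlation between genes. There were 58 calls with fry (40 of the 53 kept), 46 with quantile normalization (45 kept), 50 with the replicate block (48 kept), 51 with slide as a random block (51 kept) and 48 without the odd array (47 kept), none in the opposite direction.

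Some named genes changed sign. Between types 4 and 1, Cd14 (0.53), Prom2 (0.30) and Zeb1 (-0.54) did with slide as a block, Dusp6 (0.34), Krt19 (-0.39) and P4ha2 (-0.27) in B6TS4 alone, Ccnd1 (0.16), Mmp9 (0.32), Rhox6 (-0.34), Rhox9 (-0.0173) and Zic3 (0.18) in EGFP-TS3.5 alone, and Grhl2 (0.10), Laptm5 (-1.25) and Zeb1 (-0.76) in XGFP alone. Between types 2 and 1, Dppa5a (-0.14) and Slc2a3 (-0.22) did in B6TS4 alone. Between types 4 and 2, Ascl2 (-0.37) and Zic3 (1.00) did in EGFP-TS3.5 alone, and Eng (-0.32), Nr0b1 (-0.38), Plvap (-1.05), Robo4 (-0.97), Sox21 (0.27) and St14 (0.29) in XGFP alone. In B6 alone Cited1 (0.0224) did between EPC and ExE, and Cdkn1c (0.28) between type 1 and ExE. The other values of named genes kept their sign where called, over all alternatives: 2203 between types 4 and 1 kept their side of the threshold, 336 lost the call and 11 gained one. The same 3 counts were 1710, 140 and 6 between types 4 and 2, 1002, 249 and 0 between types 2 and 1, 2088, 51 and 2 between EPC and ExE, 1430, 98 and 5 for the defined line, and 2424, 81 and 6 between type 1 and ExE.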

Other observations

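The gene lists in this part were fixed before the data were examined, and the tests with a slide block and of the odd array were chosen only after its values were seen.

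Genes of primitive and extraembryonic endoderm, a lineage beside the trophoblast, went both ways between type 1 colonies and ExE, with 3 of 22 higher and 5 lower (2 and 3 adjusted over the list alone). The endoderm regulators Gata4 and Gata6 were higher in the colonies by 2.80 ± 0.62 (5 of 6 ExE arrays) and 2.61 ± 0.85 (5 of 6 ExE arrays), and so was the basement membrane collagen Col4a2 (1.80 ± 0.72). Spink1, a trypsin inhibitor, was lower (-3.86 ± 0.70, 3 of 10 type 1 arrays), as was Cited1, a transcription cofactor (-1.97 ± 0.29). The list as a whole had a median fold of -0.73 and a mean fold of -0.29, while the camera test on the moderated statistics pointed up (camera adjusted p = 0.945). Of 24 genes of the unfolded protein response and amino acid stress, 3 rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.426 for the list). Cth, an enzyme of cysteine synthesis, fell by 1.95 ± 0.40, Phgdh, the first enzyme of serine synthesis, fell by 1.45 ± 0.17, and the lipoprotein receptor Vldlr rose by 1.81 ± 0.40. Of 3 X and Y linked genes Ddx3y, on the Y chromosome, was lower (-4.21 ± 1.40, 3 of 10 type 1 and 3 of 6 ExE arrays, adjusted p = 0.8 for the list).

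In the ectoplacental cone 3 of the 22 endoderm genes were lower than in ExE and none higher (the same adjusted over the list alone, camera adjusted p = 0.109). They were Rbp4, the retinol carrier (-5.13 ± 0.40, 3 of 6 EPC arrays), Cited1 (-2.34 ± 0.32, although 0.0224 in B6) and Amn, an endocytic receptor subunit (-1.97 ± 0.63). Of the stress genes 3 rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.459 for the list). Chac1, which degrades glutathione, fell by 3.52 ± 0.80 and Cth by 1.85 ± 0.44, while Xbp1, a transcription factor of secretory cells, rose by 1.49 ± 0.28 and Atf5 by 1.04 ± 0.38.

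Of the stress genes 1 of 24 rose in type 4 beside type 1 (2 adjusted over the list alone), Trib3, an inhibitor in the ATF4 response (1.60 ± 0.37, adjusted p = 0.0728 for the list). Among endoderm genes Trf, the iron carrier transferrin, rose (2.31 ± 0.70, adjusted p = 0.247 for the list). Of 20 leukocyte and blood genes 2 rose, among them Laptm5, of lysosomes (2.05 ± 0.57, 7 of 11 type 4 and 1 of 10 type 1 arrays, although -1.25 in XGFP), and Cd14 fell (-1.39 ± 0.41, 3 of 11 type 4 and 8 of 10 type 1 arrays, although 0.53 with a slide block in B6TS4 and XGFP), with adjusted p = 0.944 for the list.

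The scanner file of EGFP-TS3.5 type 1 replicate 2 correlated at 0.186 and 0.185 with the other type 1 arrays of its line and at up to 0.426 with type 2 (probes centred on their median over all arrays). The value column with its label correlated at 0.428 and 0.459 with those type 1 arrays.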
